A study of Mus musculus with 4 samples.

How the data were processed

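Poly(A) RNA from cultured oesophageal cells of C57BL/6J mice was sequenced in 4 libraries, 2 from wild-type cells and 2 from cells heterozygous for the E79Q substitution in Nfe2l2, the gene of the transcription factor NRF2. Groups and replicate numbers were taken from the sample titles. The series' design text speaks instead of a human breast cancer line in which another gene was targeted. It conflicts with the series title and all sample labels, which were followed. Per the file headers, every column name carries the word SV40. The labels do not explain it, and whether the cells were immortalised is not given in the sources used here. The p53 target and cell cycle values are given with this left open. Per the labels, RNA was extracted with TRIzol and libraries were made with the NEBNext Ultra kit. The submitters' processing notes name STAR 2.5.2b, Salmon 0.11.3, DESeq 1.22.2, DESeq2 and the mouse build mm9, without the role of each. The strand setting and the annotation are not given in the sources used here.

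The deposited values are log2-like variance-stabilised values, 1 per gene and library, for 24444 genes. They run from 6.90 to 18.7. A floor of 6.98 is shared by 8120 genes in all 4 libraries. In all 24444 genes the wild-type and E79Q values of replicate 1 have the same sum as those of replicate 2, to within 1.31e-13. The values had therefore been centred on the replicate number within each gene before deposit, a step that the labels do not record. The numbers pair the libraries in the deposited values for this reason. What was shared between libraries of 1 number (a day, a culture, a run) is not given in the sources used here.

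This centring removes 1 of the 2 residual degrees of freedom of each gene. Before the data were examined, the fit was set as genotype alone, without a replicate block, which counts 2 residual degrees of freedom. Once the equal sums had been seen, genotype with a replicate block, which counts 1, was used for all main results, because it matches the values as deposited. This is a departure from the plan. The planned fit is given beside it as "no replicate block". It called 6004 genes against 4388 and 17 gene lists against 23.

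Genes entered the test where the value lay at least 1 above the lowest value of the table in at least 2 libraries (10857 genes). limma 3.58.1 in R 4.3.3 was used, with lmFit, eBayes with a mean-variance trend, a two-sided moderated test and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. The prior degrees of freedom were 14.6 and the median prior SD was 0.0601, so most of the precision of each gene is borrowed from the other genes. Differences are E79Q minus wild type on the deposited log2 scale, with the moderated SE and n = 2 pairs. This scale compresses changes of genes near the floor. Ratios of normalised counts are therefore also given for some genes, computed by inverting the variance stabilisation from the floor. Counts of single libraries come from the same inversion of values already centred by pair. They are therefore approximate, and values under the floor were set to 0.

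The steps were tested on simulated data centred in the same way, in 20 draws of 10857 genes for this comparison. With no gene changed, 5.43% of raw p-values lay under 0.05 with the block and 23.5% without it. After adjustment the blocked fit still called 4.65 genes and 0.05 lists per draw on average, and the unblocked fit 0 and 0. With 4388 genes changed, 3.64% of calls were false with the block (at most 4.80%) and 20.0% without it. With 200 genes changed, the blocked fit called 139.25 genes on average, of which 20.75 were false, so the false share exceeds 5% where few genes change. It then recovered 3.7% of the changes of 0.1, 33.6% of those of 0.2, 99.7% of those of 0.5 and 100% of those of 1. The spread of these simulations was itself taken from the fitted values. With 4388 genes changed, the sizes were drawn from the fitted differences of the called genes, and all other genes were left unchanged. The false share and recovery of those draws therefore hold for changes already large enough to be called. Genes were drawn independently of each other, so the simulated list calls do not test lists whose members are correlated.

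Gene lists were fixed before the data were examined, 43 lists with 922 entries, of which 899 are in the table. Of the names missing from it, 4 were matched through older symbols (Flvcr1 as Mfsd7b, Il36g as Il1f9, Ccn1 as Cyr61, Ccn2 as Ctgf). The 38 lists with at least 3 tested members were tested with limma camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 38 lists. The mitochondrially encoded genes and the transgene names have no match in the table. Named genes are Nfe2l2 and Keap1, the 10 called genes with the largest rise and the 10 with the largest fall whose groups do not overlap (without predicted genes named Gm with digits, names ending in Rik and pseudogenes), the 4 called members with the smallest p from each list past its test, and 2 from each other list with called members. A few genes that this rule or a list would name are not reported here.

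Alternatives were no filter, a stricter filter, no mean-variance trend, robust empirical Bayes, quantile normalization, median centring, no replicate block, leaving out each library, thresholds of size and of adjusted p, an estimated inter-gene correlation, fry and camera on ranks. A fit on log2 of the back-transformed counts plus 10 was added after the data were seen.

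Read totals are not in the table. Genes seen in a single library gave whole reads, within 0.01, for 100% of such genes in each library, with size factors of 1.03 and 0.935 in wild type and 1.11 and 0.934 in E79Q. The totals estimated from them were 14.2 and 12.6 M reads in wild type and 15.2 and 13.0 M in E79Q. They are approximate because they sum counts back-transformed from centred values. The inversion did not return whole reads for genes seen in several libraries, where the shift removed by the centring is unknown. No count test was run. Per gene, the variance left between pairs was 1.74 times counting noise under 100 normalised counts and 12.7 times above 10000, so the replicates are not 1 library deposited more than once. Nothing in the labels says that they came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. Reads of near-identical gene copies (Gsta, Ugt1a, Hspa1, tubulin, ferritin, histone and ribosomal protein families) and of overlapping genes may be split uncertainly. Figures were drawn with matplotlib 3.10.9.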

Results

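Gene expression was measured by poly(A) RNA sequencing in cultured mouse oesophageal cells, in 2 wild-type libraries and 2 libraries heterozygous for NRF2 E79Q. NRF2, encoded by Nfe2l2, is the transcription factor that drives antioxidant and detoxification genes. KEAP1 binds it and promotes its degradation. The E79Q change is a tumour-derived mutation, and the series concerns mice that carry it, with their upper digestive tract and white fat. The comparison asks which transcripts differ between E79Q and wild-type oesophageal cells. The estimated depth was 14.2 and 12.6 M reads in the wild-type libraries and 15.2 and 13.0 M in the E79Q libraries. Values are deposited variance-stabilised log2 values, and differences are E79Q minus wild type ± SE over 2 replicate pairs.

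The targeted gene itself was not called. Nfe2l2 lay at 11.38 and 11.27 in wild type and at 11.17 and 11.27 in E79Q, a difference of -0.10 ± 0.05 (limma adjusted p = 0.154). It was called lower after quantile normalization (-0.13, adjusted p = 0.0496) and when replicate 2 of either genotype was left out (-0.15), with an adjusted p of 0.0160 without wild-type replicate 2 and 0.0139 without E79Q replicate 2. Because E79Q is a substitution, the level of Nfe2l2 does not check the genotype labels. Keap1 fell by 0.18 ± 0.05 (limma adjusted p = 0.0151) and was lower in both pairs.

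NRF2 target genes and epidermal stress genes were higher in E79Q cells, and extracellular matrix genes were lower. Of 10857 genes tested, 4388 (40.4%) were called, 2333 higher and 2055 lower in E79Q. Which direction held more calls depended on the scaling, with 2048 higher and 2313 lower after median centring and 2155 higher and 2269 lower after quantile normalization. Most changes were small, with a median absolute difference of 0.25 among called genes. A difference of at least 1 was reached by 47 genes called higher and 30 called lower. On the deposited scale, the largest rises by the rule for named genes were in Nqo1, a quinone reductase (2.23 ± 0.06, an 8.74-fold ratio of normalised counts), Gsta3, a glutathione transferase (2.18 ± 0.05, 6.45-fold), Il1f9, the cytokine IL-36 gamma (2.15 ± 0.07, 48.6-fold), Gclc, the catalytic subunit of the first enzyme of glutathione synthesis (1.94 ± 0.05, 4.15-fold), and Ptgr1, a reductase of prostaglandins and leukotrienes (1.90 ± 0.05, 4.82-fold). Aldh3a1, Epgn, Cbr3, Areg and Blvrb followed, between 1.62 and 1.81. The scale compresses low genes, so ratios of normalised counts order these genes differently, and Il1f9 and Aldh3a1 (11.4-fold) lie above Nqo1 by ratio. The largest falls on the same scale were in Xist (-4.87 ± 0.07) and H19 (-2.45 ± 0.08, 12.9-fold lower), both long non-coding RNAs, then in Col5a1, a fibrillar collagen chain (-1.92 ± 0.07, 24.0-fold lower), Vim, the intermediate filament vimentin (-1.62 ± 0.07, 7.58-fold lower), Clu (-1.43 ± 0.05) and Glul, glutamine synthetase (-1.41 ± 0.05). Gfra2, Tuba1a, Col8a1 and Pcdh19 fell by between 1.32 and 1.38. The groups did not overlap in 8594 genes (79.2%), against 50% by chance in values centred by pair. No exact test of 2 pairs can give a two-sided p under 0.5, so these calls rest on the spread pooled over genes. The planned fit without the replicate block called 6004 genes, 3122 higher and 2882 lower.

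**Figure D1:**
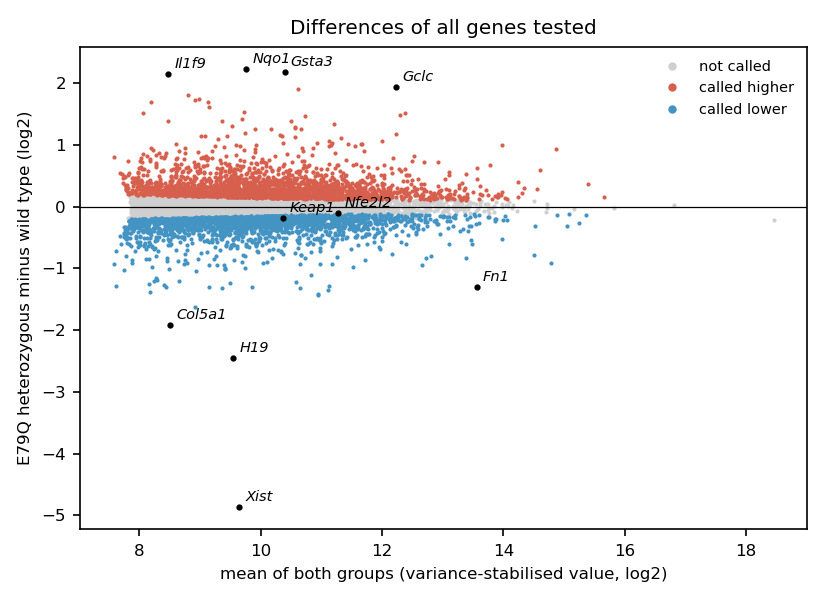
Difference between E79Q and wild-type cells (log2) against the mean value (log2) for the 10857 genes tested, each point 1 gene, with called genes coloured by direction. Nqo1, Gsta3, Il1f9 and Gclc lie highest, Xist and H19 lowest, and Nfe2l2 and Keap1 lie near 0.

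NRF2 core targets rose as a group. Of 21 tested members, 19 were called higher and 0 lower over all genes tested, and the same numbers held when adjusted over the list alone; the median difference was 0.63. Besides Nqo1 and Gclc, the cystine transporter gene Slc7a11 rose by 1.53 ± 0.04 (3.04-fold) and Gclm, the modifier subunit of the Gclc enzyme, by 1.39 ± 0.05 (3.19-fold). The mean of the members, each relative to its own mean over the libraries, was -0.44 and -0.45 in the wild-type libraries and 0.44 and 0.45 in the E79Q libraries. These values mirror each other within a pair because the deposited values were centred by pair. Camera at the preset correlation gave an adjusted p of 7.94e-18, and adjusted p = 0.553 with an estimated correlation. That second test, on 1 residual degree of freedom, called 0 of the 38 lists, 0 also at an unadjusted p under 0.05. The correlation estimated for the core list, 0.00952, was close to the preset 0.01, so this estimate does not account for its loss of the call. The second test therefore cannot decide whether correlation undoes a list. Estimates were far above the preset in some lists, such as stress keratins (0.667) and interferon response (0.616). On 1 residual per gene, each estimate reflects only how many members have residuals of the same sign, not the size of a correlation. In any list whose members are correlated the p at the preset correlation may be too small. These estimates cannot tell which lists those are.

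**Figure D2:**
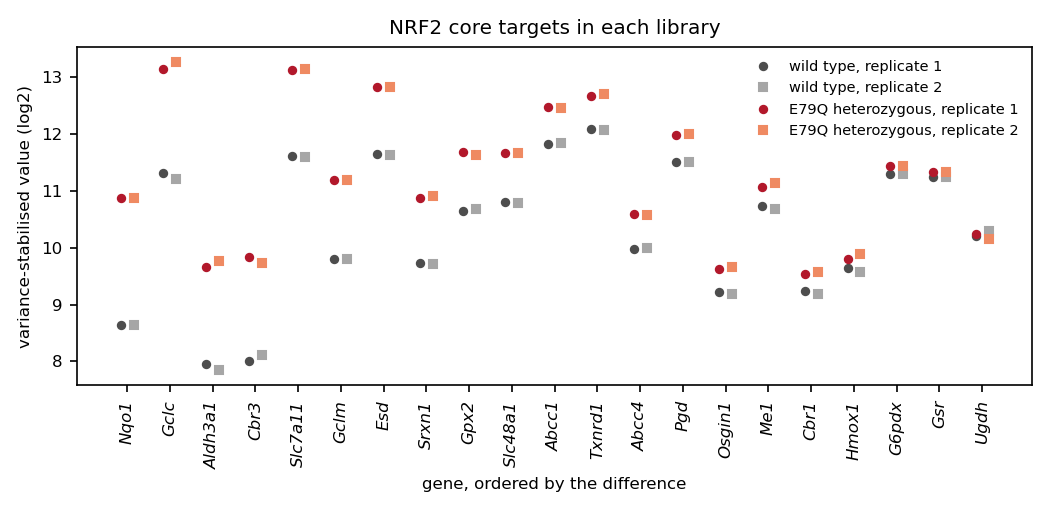
Deposited variance-stabilised value (log2) of each of the 21 tested NRF2 core targets in each of the 4 libraries, each point 1 library, ordered by the difference. Both E79Q libraries lie above both wild-type libraries in the 19 called genes, by 2.23 in Nqo1.

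Related enzyme lists rose too, and they share members with the core list. Genes of glutathione synthesis and use had 16 called higher and 1 lower of 27 tested (16 higher and 2 lower adjusted over the list alone), with a median of 0.50. Gsta3 belongs to a family of close copies, so its value is uncertain. Phase I and II detoxification had 14 higher and 1 lower of 21 (14 and 2 adjusted over the list alone), with a median of 0.35, led by Nqo1, Ptgr1, Aldh3a1, an aldehyde dehydrogenase (1.81 ± 0.07), and Cbr3, a carbonyl reductase (1.73 ± 0.07). Camera gave adjusted p-values of 5.55e-10 and 2.15e-06 for these lists, and for both the adjusted p = 0.553 with an estimated correlation. In the thioredoxin and peroxiredoxin list 7 rose and 3 fell of 18 (8 and 3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0683). Its members Srxn1, sulfiredoxin, and Cat, catalase, rose by 1.17 ± 0.05 and 1.06 ± 0.05. In the list of NRF2 and its partners, 6 rose and 3 fell of 13 (7 and 3 adjusted over the list alone; camera adjusted p = 0.0795), with Mafk, a partner of NRF2 on DNA, up by 0.75 ± 0.05 and Sqstm1, an autophagy receptor that binds KEAP1, up by 0.72 ± 0.05.

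Smaller NRF2-linked lists passed with the block and not without it. Iron and haem handling had 6 higher and 2 lower of 13 (6 and 3 adjusted over the list alone), including Blvrb (1.62 ± 0.06), Ftl1 (0.94 ± 0.04), which encodes ferritin light chain, the haem transporter gene Slc48a1 (0.87 ± 0.05) and Fth1, ferritin heavy chain (0.63 ± 0.05). NADPH and pentose phosphate genes had 7 higher and 2 lower of 13, the same adjusted over the list alone, with Rpia at 0.63 ± 0.06 and Tkt, transketolase, at 0.53 ± 0.04. The ABC transporters had 4 higher and 2 lower of 7, likewise adjusted over the list alone, with Abcc3 at 1.15 ± 0.06 and Abcc1 at 0.63 ± 0.05. AhR targets had 4 higher and 1 lower of 6, also adjusted over the list alone, but Nqo1, Aldh3a1 and Ugt1a6a stand in other lists too. Of the remaining called members Tiparp rose by 0.44 ± 0.07, and Cyp1b1, a classical target of the aryl hydrocarbon receptor, fell by 0.85 ± 0.08. The uncertain family member Ugt1a6a rose by 1.15 ± 0.07. Camera gave adjusted p-values of 0.0182, 0.0182, 0.0293 and 0.00225 for these 4 lists in turn. Without the replicate block they were 0.190, 0.0845, 0.0788 and 0.0534, with camera on ranks 0.163, 0.0731, 0.152 and 0.0543, and for each list the adjusted p = 0.553 with an estimated correlation. Genes of serine and one-carbon metabolism and ATF4 targets had 12 higher and 1 lower of 24 (13 and 2 adjusted over the list alone; camera adjusted p = 0.00234, and adjusted p = 0.553 with an estimated correlation). In that list Trib3 rose by 0.82 ± 0.05, Aldh1l2 by 0.70 ± 0.05 and Slc1a4 by 0.62 ± 0.05, while Ddit4 fell by 0.86 ± 0.05.

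Epidermal stress and inflammation genes were higher in E79Q cells. All 12 tested members of the stress keratin and hyperproliferation list were called higher, also adjusted over the list alone, with a median of 1.03. Il1f9 was joined by Hbegf, an EGFR ligand (1.54 ± 0.10), Slpi, a protease inhibitor (1.27 ± 0.07), and Krt16, a keratin of stressed epidermis (1.27 ± 0.06). Areg and Epgn, EGFR ligands too, rose by 1.70 ± 0.11 and 1.74 ± 0.09. Immediate early genes, which also respond to the handling of cells, moved with this group: 12 were higher and 2 lower of 16 (12 and 3 adjusted over the list alone), with a median of 0.60, Fos up by 1.15 ± 0.08 and Myc by 0.99 ± 0.07. Inflammatory genes had 15 higher and 4 lower of 24 (15 and 5 adjusted over the list alone). Ptgs2, the inducible cyclooxygenase, rose by 1.49 ± 0.11 and Cxcl1 by 1.03 ± 0.08, whereas Csf1 fell by 0.92 ± 0.07. Ptgs2 was no longer called with robust empirical Bayes (adjusted p = 0.161). Interferon response genes had 22 higher and 2 lower of 29 (24 and 2 adjusted over the list alone), with Rsad2 at 0.95 ± 0.07 and Oas3 at 0.78 ± 0.08. Camera gave adjusted p-values of 2.19e-11, 1.04e-05, 0.00234 and 4.14e-07 for these 4 lists in turn, and adjusted p = 0.553, 0.565, 0.589 and 0.589 with an estimated correlation.

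Differentiation markers moved unevenly. The suprabasal oesophageal list had 9 higher and 0 lower of 15 (9 and 2 adjusted over the list alone; camera adjusted p = 0.00542, 0.0858 without the replicate block, and adjusted p = 0.565 with an estimated correlation). Serpinb2 rose by 1.26 ± 0.12 but was not called with robust empirical Bayes (adjusted p = 0.195). Sbsn rose by 0.78 ± 0.06 and Dsg3, a desmosomal cadherin, by 0.74 ± 0.05. Basal keratinocyte genes had 8 higher and 6 lower of 21, the same adjusted over the list alone, and did not pass (camera adjusted p = 0.670). Itga6, an integrin of basal cells, rose by 0.73 ± 0.06, and Krt15 fell by 0.58 ± 0.07. Of the cornified envelope genes only 6 were high enough to test, with 3 higher and 1 lower, likewise adjusted over the list alone (camera adjusted p = 0.533). Keratins of simple epithelium fell, with 5 lower and 1 higher of 7, the same adjusted over the list alone. Krt8 fell by 0.94 ± 0.04 and Krt7 by 0.83 ± 0.04 (camera adjusted p = 0.000982 for the list, and adjusted p = 0.553 with an estimated correlation).

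Matrix and mesenchymal genes were lower in E79Q cells. The extracellular matrix list had 13 lower and 2 higher of 16, the same adjusted over the list alone, with a median of -0.56. Besides Col5a1, Col1a1 fell by 1.29 ± 0.07 (a 7.84-fold lower normalised count), Sparc by 1.29 ± 0.07 and Loxl2, a collagen cross-linking enzyme, by 1.21 ± 0.07. The list of EMT and TGF-beta targets had 9 lower and 2 higher of 18 (10 and 3 adjusted over the list alone), and in it Cdh2, N-cadherin, fell by 1.30 ± 0.06, Fn1, fibronectin, by 1.30 ± 0.05 and Tnc, tenascin C, to a 2.72-fold lower normalised count. Of muscle markers 3 were tested and 2 were lower, also adjusted over the list alone: Acta2, smooth muscle actin, fell by 1.23 ± 0.06 and Tagln by 0.61 ± 0.07. Camera gave adjusted p-values of 2.11e-08, 0.000347 and 0.00948 for these 3 lists in turn, and for each the adjusted p = 0.553 with an estimated correlation. The muscle list was not called without the replicate block (adjusted p = 0.0788), with camera on ranks (0.0709) or without a filter (0.220). Of 18 fibroblast markers 3 were tested, with Col1a1 and Fbln2 called lower and Fbln1 higher, likewise adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0682).

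Proliferation and lipid synthesis genes were modestly lower. G2/M genes had 24 lower and 0 higher of 37 (26 and 0 adjusted over the list alone), with a median of -0.21. Cenpf and Plk1, which act in mitosis, each fell by 0.46, with SEs of 0.05 and 0.06. S phase genes had 9 lower and 2 higher of 30, the same adjusted over the list alone, and did not pass (camera adjusted p = 0.0740); Tyms fell by 0.52 ± 0.06. Cholesterol synthesis genes had 16 lower and 2 higher of 23 (16 and 3 adjusted over the list alone), with Mvd at -0.83 ± 0.06 and Idi1 at -0.52 ± 0.05. Fatty acid synthesis genes had 10 lower and 1 higher of 16 (10 and 2 adjusted over the list alone), with Scd2, a fatty acid desaturase, at -0.90 ± 0.06 and Fasn, fatty acid synthase, at -0.79 ± 0.04. Proteasome subunits had 14 lower and 0 higher of 31 (15 and 0 adjusted over the list alone), by no more than 0.31 in Psmc3. Camera gave adjusted p-values of 2.70e-09, 1.65e-06, 5.34e-05 and 0.000307 for the G2/M, cholesterol, fatty acid and proteasome lists, and adjusted p = 0.553, 0.553, 0.565 and 0.553 with an estimated correlation.

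Unfolded protein response genes had 15 higher and 0 lower of 21 (16 and 0 adjusted over the list alone), with Atf6 at 0.62 ± 0.05 and the chaperone gene Hspa5 at 0.59 ± 0.05. Ribosomal protein genes had 15 higher and 1 lower of 35, the same adjusted over the list alone, none by more than 0.23. Camera gave adjusted p-values of 1.65e-06 and 0.00234 for these lists, and adjusted p = 0.553 and 0.654 with an estimated correlation. In all, 23 of 38 lists passed, 15 up and 8 down.

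Most called members that went against their list are named here after their values were seen. Among the lists that rose, Gpx1, a glutathione peroxidase, fell by 0.21 ± 0.05, the carbonyl reductase gene Cbr2 by 0.38 ± 0.05 and Idh1, an NADPH-producing isocitrate dehydrogenase, by 0.39 ± 0.06. Slc40a1, the iron exporter ferroportin, fell by 0.21 ± 0.07 and Tfrc, the transferrin receptor, by 0.16 ± 0.06. H6pd, Abcc5, Abcg2, Gbp2, Ifit2, Jund, Cyr61 and Rpl7 fell by between 0.15 and 0.34. Of the inflammatory list Cxcl5 fell by 0.70 ± 0.06, Il18 by 0.63 ± 0.08 and Ccl2 by 0.49 ± 0.07. Among the lists that fell, Plaur, the urokinase receptor, rose by 0.71 ± 0.10, Snai2, a repressor of epithelial genes, by 0.27 ± 0.06 and Krt20 by 0.27 ± 0.08. Dhcr7, Col4a2, Agpat2 and Tgfb1 rose by between 0.17 and 0.23.

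**Figure D3:**
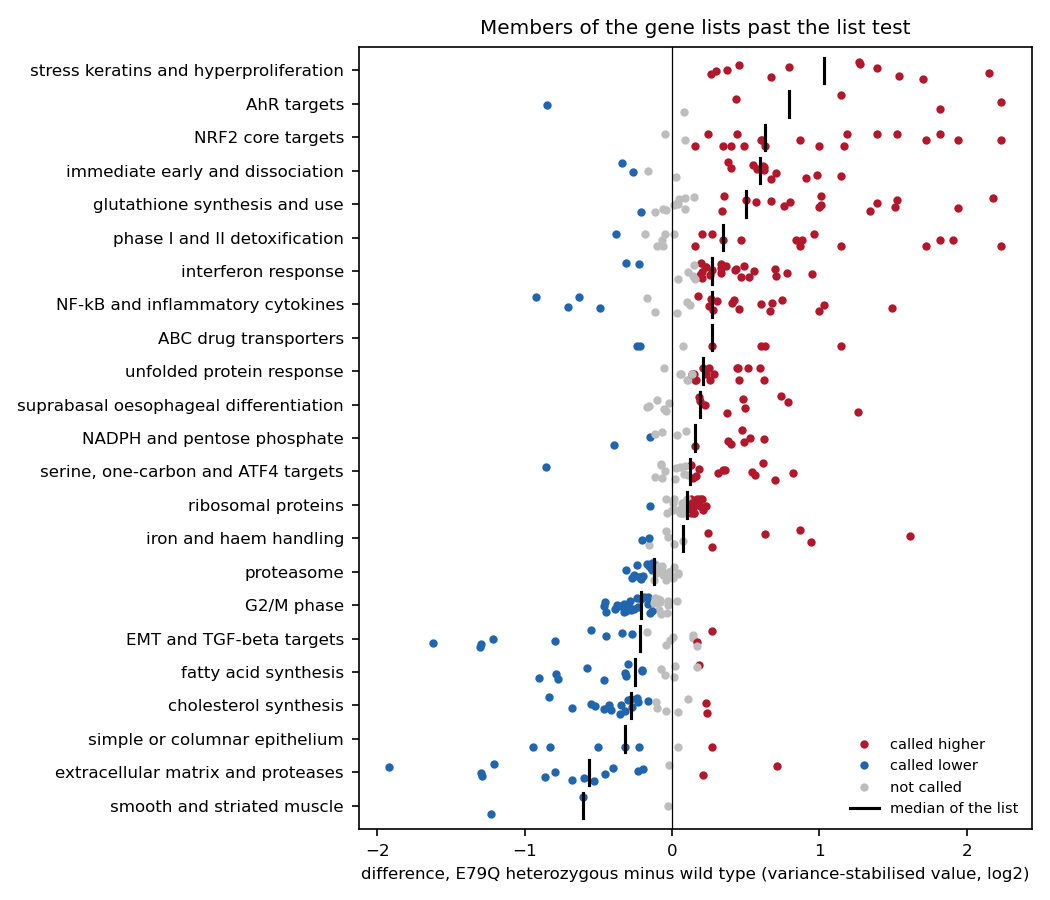
Difference between E79Q and wild-type cells (log2) of every tested member of the 23 lists that passed camera at the preset correlation, each point 1 gene coloured by its call, with the median of each list as a bar. Stress keratins have the highest median, 1.03, and muscle markers, with 3 tested genes, the lowest, -0.61.

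The other lists did not pass and held calls in both directions or few tested genes. Heat shock genes had 4 higher and 7 lower of 15 (4 and 8 adjusted over the list alone; camera adjusted p = 0.180), and Hspa8 fell by 0.61 ± 0.05. Hypoxia and glycolysis genes had 10 higher and 8 lower of 23, the same adjusted over the list alone (camera adjusted p = 0.533), with Hk2 and Vegfa each at 1.03 ± 0.06. p53 targets had 5 higher and 6 lower of 22 (5 and 7 adjusted over the list alone; camera adjusted p = 0.691), with Gdf15, a secreted hormone that lowers food intake, at 0.68 ± 0.06. Notch genes had 4 higher and 4 lower of 10 (5 and 4 adjusted over the list alone; camera adjusted p = 0.820), with Jag1 at 0.66 ± 0.06. Fatty acid oxidation had 3 higher and 6 lower of 16 (3 and 7 adjusted over the list alone; camera adjusted p = 0.0808), with Cpt1a at -0.62 ± 0.05 and Ppard at 0.84 ± 0.07. Secreted metabolic hormones had 6 higher and 4 lower of 14, the same adjusted over the list alone (camera adjusted p = 0.691), and Igf2 fell by 1.25 ± 0.07. Neural markers had 0 higher and 2 lower of 3 (1 and 2 adjusted over the list alone; camera adjusted p = 0.393), and histones 0 higher and 1 lower of 3 (0 and 2 adjusted over the list alone; camera adjusted p = 0.165). Leukocyte, adipocyte and endothelial markers each had 2 tested genes, too few for the list test. Both leukocyte markers were higher, Cd68 by 0.67 ± 0.07 and Cd74 by 0.21 ± 0.08, the second no longer called without a filter (adjusted p = 0.0659) or after median centring (0.0508), and the adipocyte marker Cebpa fell by 0.41 ± 0.06; no endothelial marker was called, over all genes or adjusted over the list alone. The median and mean of a list differed in sign for basal keratinocyte genes, p53 targets and sex chromosome markers.

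Xist, the RNA that coats an inactive X chromosome, separated the genotypes. It lay at 11.99 and 12.17 in wild type and at 7.30 and 7.12 in E79Q, close to the floor of 6.98. Tsix, which overlaps it on the opposite strand and cannot be told apart without strand, fell by 1.28 ± 0.08. The sex chromosome list, with 2 higher and 2 lower of 6, the same adjusted over the list alone, did not pass (camera adjusted p = 0.533). The Y-linked members were seen in all 4 libraries.

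Libraries grouped by genotype, but centring by pair had removed any shift shared by both libraries of a replicate number. They could therefore not group by replicate number, and the shares and correlations below do not weigh genotype against it. The first principal component held 94.1% of the variance of the tested genes and the second 5.89%, and the third is empty because of the centring by pair. Across genes, which are not independent replicates, the Pearson correlation was 0.999 between libraries of 1 genotype and between 0.975 and 0.981 across genotypes. The differences in pair 1 and pair 2 had a Pearson correlation of 0.880 across genes.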

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

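All alternatives were set before the data were examined except the fit on back-transformed counts (4380 genes called), which was chosen after seeing the data. No named gene or list reversed under any alternative. The fit with no replicate block called 6004 genes, 3122 higher and 2882 lower, of which 4052 were among the 4388 called with the block. It called 17 lists and ended the call of 6 lists (iron, NADPH, ABC transporter, AhR, suprabasal and muscle) and of no named gene; camera on ranks ended 5 of these calls, all but the suprabasal one. Changed genes numbered between 3593 with the stricter filter and 4424 with quantile normalization over the filters, variance settings and normalizations. Requiring a difference of at least 1 left 77 genes and testing against 0.5 left 196, by construction of the thresholds. Leaving out 1 library, fitted without the block on 1 residual degree of freedom with the lone sample assumed to vary like the other group, gave 5008 to 5463 changed genes and 23 lists each time. The values left still carry the omitted library through the centring by pair, so this says little about stability. Nfe2l2 then ranged from -0.153 to -0.0499 and was called lower without replicate 2 of either genotype; it was also called at -0.13 after quantile normalization. The cause was not tested. Camera with an estimated correlation called 0 lists (0 at an unadjusted p under 0.05), and fry, which tests a list by itself, also called 0 (19 at an unadjusted p under 0.05, smallest adjusted p 0.0685), while its mixed test, for change in either direction, called 8. Both had 1 residual degree of freedom. The E79Q minus wild-type difference of the core target score was 0.90, 0.64 with the median over members and 0.88 after median centring. The first component held 98.7% of the variance of the 500 most variable genes, likewise after the centring by pair. Over all alternatives, 1490 of 1498 comparisons of named genes and 505 of 566 of lists stayed on the same side of the threshold. A call was lost in 5 and 58. These totals are a poor measure of stability. Named genes were mostly picked as called genes with large changes or small p, and both totals include the fits that left out 1 library. Lists not called in the main fit also count as unchanged under the tests that called 0 lists. In simulated data with 200 genes changed, changes of 0.1 were mostly missed (3.7% recovered). With 4388 genes changed, 83.7% of the changed genes were called, not split by size. Those sizes were drawn from the called genes, so this share does not give the power for smaller changes. Depth was not varied.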

Other observations

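All tests of technical explanations below, and the choice of the imprinted, EGFR ligand and MAPK feedback lists, were made after the data had been seen. The predictions for windows of neighbouring genes, for the other imprinted genes and for the MAPK feedback genes were written before their own values were seen. Genes named here outside the fixed lists were chosen after their values were seen.

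EGFR ligands were gathered into a list after most of them had been seen to rise, so their count is no independent evidence. All 6 tested ligands were called higher, with a median of 1.46, from Epgn, Areg, Hbegf and Ereg (1.39 ± 0.10) to Btc and Tgfa, both at 0.30. One hypothesis was that genes induced as feedback by MAPK signalling, which lies downstream of EGFR, rise with the ligands. Of 9 tested feedback genes 8 were called higher and 0 lower, with a median of 0.64. Dusp6 rose by 0.997 ± 0.084, Etv5 by 0.91 ± 0.07, Dusp5 by 0.90 ± 0.07 and Spry2 by 0.70 ± 0.09. Camera at the preset correlation gave p = 7.47e-07, and p = 0.336 with an estimated correlation. Higher MAPK output in E79Q cultures may therefore accompany the ligands. The immediate early genes moved the same way, so a difference in culture state or medium stays open.

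H19, Igf2 and Mest, 3 imprinted genes, fell by 2.45 ± 0.08, 1.25 ± 0.07 and 1.20 ± 0.08. The hypothesis that the fall extends to other imprinted genes was not borne out. The other 10 tested had a median of -0.0394, with 3 called higher and 3 lower. Camera at the preset correlation gave p = 0.469 for them. Grb10 fell by 0.95 ± 0.06 and Phlda2 rose by 0.52 ± 0.08.

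Xist stood at 3809 and 4348 normalised counts in wild type and at 6.25 and 1.19 in E79Q. These counts were back-transformed from values centred by pair and are approximate. The 4 Y-linked genes were seen in all libraries and lay higher in E79Q by 0.54 ± 0.07 (Ddx3y), 0.31 ± 0.07 (Uty), 0.13 ± 0.06 (Kdm5d) and 0.06 ± 0.06 (Eif2s3y), of which the first pair were called. Silencing of a single X in wild-type cells would put X-linked genes lower there. The median difference of 327 X-linked genes lay -0.0286 from that of autosomal genes (bootstrap 95% interval -0.0573 to -0.00191). This argues against silencing along the whole of a single X. It cannot decide on an extra X that is silenced, which would leave X-linked values about unchanged. A mixture of male and female cells in the wild-type culture cannot be told apart from male cells with raised Xist, because the smallest Y-linked difference was 0.965 standard errors above 0 and excludes neither. Female cells would also lower the Y-linked genes by about a common amount. The unequal differences argue against a mixture as the whole source of these, though not against a small share of female cells as the source of Xist. The sex of the animals and the origin of each line were not tested and may differ between genotypes.

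Mesenchymal genes were lower in E79Q. Fibroblasts in the wild-type culture are a candidate source. Dcn, Lum, Col1a2, Col3a1 and Pdgfra together fell by a net 22.3 normalised counts, 0.198% of the fall of Fn1 (11256). Counts in this paragraph were back-transformed from values centred by pair and are approximate. Lum was at 0 in all libraries, and Dcn was at or near 0 in wild type and higher in E79Q. This argues against fibroblasts that express Dcn and Lum as the source of the Fn1 fall. The sum leaves out 3 tested genes of the fixed fibroblast list. Of these Col1a1 fell from 305 and 333 to 44.9 and 36.7 counts and Fbln2 from 2072 and 2066 to 1379 and 1383, while Fbln1 rose. Other fibroblasts therefore stay open. Scaling between libraries is argued against by the median of the matrix list after quantile normalization, -0.58. A difference between the cell lines that is unrelated to E79Q may also account for the fall and was not tested, since the labels name no independent lines.

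Stress keratin and EGFR ligand genes were higher in E79Q. The stress list, fixed before the data were examined, had a median of 0.943 in pair 1 (bootstrap 95% interval over members 0.275 to 1.20) and 1.11 in pair 2. All 12 tested members were above 0 in both pairs, the smallest at 0.220, so the interval could not reach 0 and adds no evidence. Members of a list are also not replicates. The rise in both pairs itself argues against a culture state in 1 replicate pair as the whole source. A stricter bound tried first, 0.557 (0.5 of the pair 2 median), lies inside the bootstrap interval. Areg (1.34 and 2.07), Hbegf (1.23 and 1.85) and Ereg (1.06 and 1.71) rose more in pair 2, and Krt6b slightly less (0.823 and 0.770). A part played by such a state therefore stays open. A response to handling cannot be told apart from genotype, because the immediate early list rose as well (median 0.60) and how the cultures of each genotype were handled is not given in the sources used here.

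Differences along the genome were examined for 10671 genes with a chromosome in the GENCODE M21 annotation. Among the autosomes and the X no median lay beyond 0.0701 from 0. This argues against the gain or loss of an autosome, or of an active X, in most cells of either genotype. An extra X that is inactive would leave X-linked values about unchanged, so the X median cannot decide on it. If expression followed copy number, 1 extra copy of 2 would give 0.58 on a plain log2 scale. It would give less on the deposited scale, which compresses low genes. Loss of the Y in some wild-type cells would move the 4 tested Y-linked genes by about a common amount, somewhat less for lower genes on this scale. The largest and smallest differences lay 0.488 apart, with 95% intervals that do not meet (Ddx3y 0.401 to 0.688, Eif2s3y -0.067 to 0.179), and an F test of 1 shared amount, with genes taken as independent, rejected it (F = 11.5). The test leaves out the compression of the scale, but Eif2s3y, the highest of these genes in wild type, would be compressed least and moved least. This argues against loss of the Y as the whole source of these differences. The bound tried first, a median within 0.2 of 0, was not met (0.221). Loss in a small share of cells, within the interval of Eif2s3y, stays open. The largest absolute median over 50 neighbouring genes was 0.18, on chromosome 5 from Polr2j to A430033K04Rik, where values were lower in E79Q. None of 1000 shuffles of gene order reached it (percentile 95 of their largest values, 0.136). Windows on 3 other chromosomes also passed that level, 7 (0.154) and 18 (0.140), higher in E79Q, and 19 (-0.146), lower. This is what a copy-number difference of a region, in some of the cells, might give. Neighbouring genes that are regulated together would give the same result and were not separated from it.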
